A study of Homo sapiens with 18 samples.

How the data were processed

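Strand-specific libraries of total RNA were made from HT1080-ST cells, a human fibrosarcoma line, and sequenced, per the labels' protocols. The 18 libraries fall into 6 groups of 3: untreated cells, cells given the vehicle dimethyl sulfoxide (DMSO), and cells given PhenDC3, PhenDC6, pyridostatin (PDS) or BisQn, a bisquinolinium control compound. Each compound was used at 10 µM from a DMSO stock, and the labels give 24 h for all groups. The treatment protocol names 3 culture plates per compound and 3 for DMSO, so the p-values measure the spread between plates of 1 cell line.

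The authors deposited raw read counts per gene for all libraries in a single table of 57820 Ensembl gene identifiers, with no normalization. Per the submitters' processing notes, the tools were STAR 2.7, Picard 1.9.2, SAMtools 1.4 and featureCounts 1.5.0 with the hg19 build; their settings, the gene annotation and the use of strand in counting are not given in the sources used here. Reads of overlapping or antisense genes, and of genes with near-identical copies, therefore may have been assigned to either partner. Symbols came from a table of gene names (51996 identifiers matched) or from GENCODE release 29 (342 more); 5482 identifiers had no symbol. No row named anything but a gene. Because that reference is of another build, gene positions were not used to assign reads or find promoters. Its transcript sequences, with 5' UTRs from its exon and coding records, gave GC content, lengths and motifs, and mitochondrial genes were put in their known order.

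Library totals ranged from 57248359 to 83611846 counted reads. Pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom between 7.2 and 27.5, so each library counted as 1 replicate. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr with its minimum count of 10, which left 24752 genes, of which 1152 had no symbol. Libraries were scaled by TMM (factors 0.927 to 1.05). A model with 1 coefficient per group was fitted to all 18 libraries, and 11 comparisons were tested, two-sided, with edgeR's quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are TMM-scaled CPM, the usual depth-scaled read count.

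The designs, the alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, called genes with a usable symbol, a mean of at least 2 CPM and no overlap between the replicates of the groups. It kept the 10 largest rises and falls for compounds against DMSO and 5 of each elsewhere. It also took the 10 genes with the largest mean change shared by the 3 ligands, and up to 4 members of each list with the lowest p. Mitochondrial, histone and ribosomal protein genes were named only within their lists, and Y-linked genes and XIST were left out. Some genes that the rule took are not reported here. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over 330 tests. Of 147 calls, 11 held when the correlation was estimated from the data, and that p is given beside each call described.

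The replicate numbers were checked for pairing through the correlation of deviations from group means. Over all tested genes, libraries with the same number correlated by 0.0575 to 0.209, against at most 0.0135 across numbers. Over 11407 genes with a mean log2 CPM above 2, the same-number correlations were 0.281 to 0.626, against at most 0.0526 across numbers. A correlation above 0.1 in every pair had been asked for, which the first set did not meet. The second set was chosen after the first had been seen, and on it the numbers were taken to pair the samples, before the calls of the fits were compared. The design without the block stayed the main one.

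Correlations of fold changes were set beside 20 simulations of unchanged groups. All 18 libraries, the DMSO libraries included, were drawn from 1 mean per gene with the fitted dispersions, so that the noise of the shared control entered every simulated comparison. Each library was drawn on its own and without the replicate block, so the simulation holds no pairing. The 3 DMSO libraries were too few to split. The test was also run on simulated data for PhenDC3 against DMSO over 24275 genes with 200 changed. It called 31 of 50 genes changed 1.3-fold, 45 of 50 at 1.5-fold, 49 of 50 at 2-fold and 50 of 50 at 4-fold, and 8 unchanged genes. Of 20 random lists camera called 0 at an unadjusted p under 0.05. Genes were drawn independently of each other there, without pairing. The random lists therefore do not speak to false list calls where genes are correlated.

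Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM), a fit of only the groups compared, the replicate block, each library left out in turn, an adjusted p under 0.01, and an absolute log2 fold change of at least 1. For lists, the estimated correlation and the rotation test fry were used. A count was taken as moved beyond 1.5 times the main count, and a correlation beyond a difference of 0.1.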

Results

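RNA was measured in HT1080-ST fibrosarcoma cells after exposure to small molecules that bind G-quadruplexes, 4-stranded structures of guanine-rich nucleic acid. The series addresses the roles of these structures in transcription. There were 3 libraries in each of 6 groups, with totals from 57248359 counted reads (untreated replicate 3) to 83611846 (PhenDC3 replicate 2). DMSO was the vehicle control, BisQn the control compound, and PhenDC3, PhenDC6 and PDS the ligands, all at 10 µM. Below, log2 fold changes carry their SE with n = 3 per group.

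Under PhenDC3, HMGCS1, an enzyme of cholesterol synthesis, fell from 547 to 152 CPM (log2 fold change -1.85 ± 0.20), and HSD17B7 from 32.3 to 8.97 CPM (-1.84 ± 0.10). MSMO1 (-1.67 ± 0.14), ACAT2 (-1.65 ± 0.19), FAM111B (-1.69 ± 0.12), KRT15 (-1.87 ± 0.14), SNCAIP (-1.75 ± 0.10) and INSC (-1.96 ± 0.17) fell as well. Among genes that the naming rule could take, the RNA SWINGN (3.60 ± 0.15) and CCT6P3 (2.97 ± 0.11) rose most. NUDT19-DT (2.94 ± 0.13), GCNA (2.72 ± 0.11), MRNIP (2.42 ± 0.13), GPR75 (2.38 ± 0.13), ZFHX2 (2.21 ± 0.18) and ZNF316 (2.16 ± 0.12) rose as well. The rule left out mitochondrial genes, of which some tRNAs rose more, such as MT-TG (3.64 ± 0.10). CCT6P3, CYP4F26P (2.36 ± 0.22), CHMP4BP1 (2.18 ± 0.13) and HSD17B7P2 (-1.93 ± 0.16) are pseudogenes, whose reads may be shared with related genes, and NUDT19-DT starts beside another gene, so it is uncertain without the counting strand. In all, 11008 of 24752 genes changed (edgeR, adjusted p under 0.05), 5454 up and 5554 down, with at least a 2-fold change in 1014 and 671 of them.

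Of 24 tested genes of cholesterol synthesis, 23 fell under PhenDC3 (23 adjusted over the list alone), with a median of -1.33 (camera adjusted p = 1.63e-24; adjusted p = 0.143 with an estimated correlation). SQLE (-1.64 ± 0.13) and STARD4 (-1.3 ± 0.08) were among them. Fatty acid synthesis fell in 11 of 12 (11 adjusted over the list alone; adjusted p = 1.29e-05, and adjusted p = 0.211 with an estimated correlation), with ELOVL5 at -0.74 ± 0.06, while SREBF1 rose by 0.54 ± 0.06. Of 57 listed replication-dependent histones 22 were tested, and these fell in 20 of 22 (20 adjusted over the list alone), with a median of -1.25 (adjusted p = 5.89e-18; adjusted p = 0.199 with an estimated correlation). G2/M genes fell in 27 of 28 (27 adjusted over the list alone; adjusted p = 1.42e-22, and adjusted p = 0.156 with an estimated correlation), among them the mitotic kinases CDK1 (-0.87 ± 0.06) and TTK (-0.94 ± 0.06). Genes of G1/S and DNA replication fell in 24 of 27 (24 adjusted over the list alone; adjusted p = 2.1e-14, and adjusted p = 0.38 with an estimated correlation), with CDC45 at -1.13 ± 0.09 and E2F1 at -1.07 ± 0.09. Homologous recombination and Fanconi genes fell in 21 of 24 (22 adjusted over the list alone; adjusted p = 1.53e-17, and adjusted p = 0.154 with an estimated correlation), with FANCI at -0.80 ± 0.06. Helicases known to act on G-quadruplexes fell in 9 of 16 and rose in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.00119, and adjusted p = 0.422 with an estimated correlation). BLM fell by 1.15 ± 0.08 and BRIP1 by 0.97 ± 0.07.

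Targets of p53 rose in 20 of 27 and fell in 3 under PhenDC3 (21 and 3 adjusted over the list alone), with a median of 0.29 (adjusted p = 1.03e-07; adjusted p = 0.107 with an estimated correlation). MDM2, the ubiquitin ligase of p53, rose by 1.09 ± 0.06 and PHLDA3 by 1.17 ± 0.07. Mitochondrially encoded mRNAs rose in 11 of 13 (11 up and 2 down adjusted over the list alone; adjusted p = 3.47e-14, and adjusted p = 0.154 with an estimated correlation). MT-CYB rose by 2.43 ± 0.09, whereas MT-ND1 stood at -0.21 ± 0.09. Genes with ZNF symbols rose in 204 of 425 and fell in 54 (211 and 57 adjusted over the list alone), with a median of 0.20 (adjusted p = 4.4e-07; adjusted p = 0.165 with an estimated correlation), such as ZNF768 (1.25 ± 0.05) and ZNF609 (1.63 ± 0.09). Ribosome biogenesis rose in 18 of 31 and fell in 4 (18 and 4 adjusted over the list alone; adjusted p = 0.0163, and adjusted p = 0.807 with an estimated correlation). Targets of NRF2 rose in 10 of 22 and fell in 6 (10 and 6 adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.718 with an estimated correlation). The NRF2 call was lost with the replicate block (adjusted p = 0.0675), without DMSO replicate 3 (0.14) and without PhenDC3 replicate 1 (0.0702), and that for ribosome biogenesis without PhenDC3 replicate 2 (0.0663). Ferritin heavy chain FTH1 (1.45 ± 0.10) and heme oxygenase HMOX1 (1.08 ± 0.11) rose. Extracellular matrix genes fell in 17 of 29 and rose in 4 (18 and 4 adjusted over the list alone; adjusted p = 0.00385, and adjusted p = 0.184 with an estimated correlation), with SPARC at -0.71 ± 0.07 and COL5A1 at 1.07 ± 0.08. Chaperones of the unfolded protein response fell in 9 of 19 and rose in 3 (10 and 4 adjusted over the list alone; adjusted p = 0.0167, and adjusted p = 0.704 with an estimated correlation), with PDIA4 at -0.67 ± 0.05. Without PhenDC3 replicate 1 the adjusted p was 0.0511. ATF4 targets had a median of -0.23 at adjusted p = 0.0622, adjusted p = 0.00822 with the replicate block, and adjusted p = 0.825 with an estimated correlation and no block.

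PhenDC6 changed fewer genes and by less. DDX42, a DEAD-box helicase, rose from 140 to 421 CPM (1.59 ± 0.06), the cytoskeletal linker PLEC from 489 to 1150 CPM (1.23 ± 0.12), and FTH1 from 26.3 to 67.9 CPM (1.37 ± 0.10). CCT6P3 (2.07 ± 0.12), SWINGN (1.94 ± 0.16), CEMIP (1.51 ± 0.17), PGBD5 (1.48 ± 0.08), MRTFA-AS1 (1.42 ± 0.16), ZNF316 (1.34 ± 0.12) and TM4SF19 (1.22 ± 0.17) rose. MRTFA-AS1 is antisense to another gene and FTH1 has near-identical copies, so both are uncertain. INSC (-1.53 ± 0.16), PCYOX1L (-1.42 ± 0.22), ESM1 (-1.16 ± 0.22), NEK3 (-1.10 ± 0.13), ZMAT1 (-1.02 ± 0.13), TNFSF8 (-1.01 ± 0.17), KRT15 (-0.94 ± 0.13), PLAT (-0.93 ± 0.15), SNCAIP (-0.90 ± 0.09) and the immune checkpoint ligand CD274 (-0.91 ± 0.07) fell. The test called 5677 genes, 2436 up and 3241 down, with at least a 2-fold change in 250 and 73. The balance depended on the filter, since 2446 rose and 2316 fell with the stricter one, and 2589 and 2643 with none.

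Under PhenDC6, G2/M genes fell in 26 of 28 (27 adjusted over the list alone; adjusted p = 2.53e-21, and adjusted p = 0.165 with an estimated correlation), with CDK1 at -0.54 ± 0.06. Genes of G1/S and DNA replication fell in 19 of 27 (24 adjusted over the list alone; adjusted p = 3.38e-08, and adjusted p = 0.574 with an estimated correlation), homologous recombination genes in 20 of 24 (20 adjusted over the list alone; adjusted p = 1.11e-11, and adjusted p = 0.256 with an estimated correlation), and histones in 20 of 22 (20 adjusted over the list alone; adjusted p = 7.16e-11, and adjusted p = 0.417 with an estimated correlation). Cholesterol synthesis fell in 13 of 24 (15 adjusted over the list alone), with a median of -0.42 (adjusted p = 6.99e-07; adjusted p = 0.569 with an estimated correlation). Lysosome and autophagy genes rose in 11 of 33 and fell in 0 (16 and 0 adjusted over the list alone; adjusted p = 1.55e-08, and adjusted p = 0.101 with an estimated correlation), with the autophagy receptor SQSTM1 at 1.14 ± 0.07 and FLCN at 0.79 ± 0.05. Mitochondrial mRNAs rose in 6 of 13 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 1.57e-08, and adjusted p = 0.291 with an estimated correlation). ATF4 targets fell in 16 of 30 and rose in 3 (18 and 3 adjusted over the list alone; adjusted p = 0.000736, and adjusted p = 0.643 with an estimated correlation), with CEBPG at -0.36 ± 0.06. The 4 tested targets of the aryl hydrocarbon receptor had 2 that fell (2 adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.188 with an estimated correlation), TIPARP (-0.38 ± 0.04) and AHRR (-0.29 ± 0.09). The list call was lost without DMSO replicate 1 (adjusted p = 0.0593) or PhenDC6 replicate 2 (0.0722), and that of AHRR without DMSO replicate 3 (0.0648), PhenDC6 replicate 2 (0.131) or PhenDC6 replicate 3 (0.06). Helicases fell in 6 of 16 (8 adjusted over the list alone; adjusted p = 0.00248, and adjusted p = 0.447 with an estimated correlation), and fatty acid synthesis in 4 of 12 with 1 rising (7 and 1 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.569 with an estimated correlation). Matrix genes fell in 11 of 29 and rose in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.311 with an estimated correlation). Ribosomal proteins fell in 11 of 82 and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.000523, and adjusted p = 0.844 with an estimated correlation), and nuclear oxidative phosphorylation fell in 8 of 31 (8 adjusted over the list alone; adjusted p = 0.00309, and adjusted p = 0.771 with an estimated correlation). NRF2 targets rose in 6 of 22 (8 up and 2 down adjusted over the list alone; adjusted p = 0.00248, and adjusted p = 0.481 with an estimated correlation). Without DMSO replicate 3 the adjusted p was 0.0754 for matrix genes and 0.0515 for NRF2 targets. For p53 targets, 6 rose and 4 fell (7 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.31).

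Under PDS, the stress cytokine GDF15 rose from 65.9 to 392 CPM (2.57 ± 0.17). PINCR, a p53-induced RNA, rose from 0.7 to 8.55 CPM (3.61 ± 0.15), and SWINGN (3.51 ± 0.15), KLLN (3.11 ± 0.16), CCT6P3 (2.83 ± 0.11), NECTIN4 (2.77 ± 0.18), GRIN2C (2.69 ± 0.15), the carboxypeptidase M gene CPM (2.57 ± 0.19) and NUPR1 (2.51 ± 0.15) rose. MIR3189 (2.46 ± 0.20) lies within GDF15, so its reads may come from that gene, and KLLN is uncertain without the counting strand. HMGCS1 (-2.35 ± 0.21), FAM111B (-2.22 ± 0.12), MSMO1 (-1.98 ± 0.14), INSIG1 (-1.92 ± 0.14), DHRS2 (-1.90 ± 0.06), LINP1 (-1.89 ± 0.13), INO80C (-1.88 ± 0.13) and SNCAIP (-1.85 ± 0.10) fell. HSPA8P5 (-1.96 ± 0.57) is a pseudogene of a chaperone gene and is uncertain. The test called 11196 genes, 5461 up and 5735 down, with at least a 2-fold change in 1085 and 690. With the stricter low-count filter the count was 7461.

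Under PDS 26 of 27 p53 targets rose (26 adjusted over the list alone), with a median of 0.84 (adjusted p = 9.18e-49; adjusted p = 0.000446 with an estimated correlation). MDM2 (1.88 ± 0.06), BTG2 (1.67 ± 0.06) and FDXR (1.65 ± 0.05) were among them. All 13 mitochondrial mRNAs rose (13 adjusted over the list alone; adjusted p = 3.47e-39, and adjusted p = 0.0263 with an estimated correlation), with MT-ND4 at 2.93 ± 0.10. Cholesterol synthesis fell in 24 of 24 (24 adjusted over the list alone), with a median of -1.42 (adjusted p = 4.22e-28; adjusted p = 0.126 with an estimated correlation), and fatty acid synthesis in 10 of 12 (10 adjusted over the list alone; adjusted p = 2.43e-08, and adjusted p = 0.126 with an estimated correlation), with FASN at -1.10 ± 0.07. Histones fell in 21 of 22 (21 adjusted over the list alone), with a median of -1.96 (adjusted p = 6.06e-37; adjusted p = 0.0957 with an estimated correlation). ATF4 targets rose in 23 of 30 and fell in 1 (23 and 1 adjusted over the list alone; adjusted p = 7.44e-07, and adjusted p = 0.43 with an estimated correlation), with STC2 at 1.17 ± 0.08 and SESN2 at 1.18 ± 0.13. Interferon response genes rose in 16 of 30 and fell in 3 (18 and 3 adjusted over the list alone; adjusted p = 0.00328, and adjusted p = 0.234 with an estimated correlation), with IFIT2 at 0.94 ± 0.09. Lysosome and autophagy genes rose in 23 of 33 and fell in 2 (23 and 3 adjusted over the list alone; adjusted p = 6.6e-07, and adjusted p = 0.138 with an estimated correlation). ZNF genes rose in 230 of 425 and fell in 42 (236 and 44 adjusted over the list alone; adjusted p = 3.24e-09, and adjusted p = 0.126 with an estimated correlation).

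G2/M genes fell in 26 of 28 under PDS (27 adjusted over the list alone; adjusted p = 2.66e-20, and adjusted p = 0.176 with an estimated correlation). Genes of G1/S and DNA replication fell in 21 of 27 and rose in 2 (21 and 3 adjusted over the list alone; adjusted p = 2.51e-10, and adjusted p = 0.494 with an estimated correlation). Homologous recombination genes fell in 15 of 24 and rose in 2 (18 and 2 adjusted over the list alone; adjusted p = 0.00523, and adjusted p = 0.771 with an estimated correlation). Helicases fell in 9 of 16 and rose in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0494, and adjusted p = 0.709 with an estimated correlation). The helicase call was lost with RLE scaling, and without DMSO replicate 2 (0.0735), DMSO replicate 3 (0.0579) or PDS replicate 1 (0.131).

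Heat shock genes fell in 10 of 17 under PDS (10 adjusted over the list alone; adjusted p = 0.00457, and adjusted p = 0.756 with an estimated correlation), among them HSP90AA1 (-0.84 ± 0.10). Splicing factors fell in 17 of 27 and rose in 4 (17 and 4 adjusted over the list alone; adjusted p = 0.00864, and adjusted p = 0.769 with an estimated correlation), with TRA2B at -0.61 ± 0.05 and TRA2A at 1.07 ± 0.05. Without PDS replicate 1 the adjusted p was 0.0643. Cytosolic ribosomal protein genes fell in 47 of 82 and rose in 2 (50 and 2 adjusted over the list alone; adjusted p = 0.00084, and adjusted p = 0.854 with an estimated correlation), with RPL22L1 at -1.01 ± 0.07. Nuclear genes of oxidative phosphorylation fell in 17 of 31 and rose in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.824 with an estimated correlation), with ATP5F1C at -0.44 ± 0.04. Without DMSO replicate 2 the adjusted p was 0.0543. Extracellular matrix (adjusted p = 0.104), hypoxia and glycolysis (adjusted p = 0.0676) and unfolded protein response genes (adjusted p = 0.196) were not called, but with the replicate block their adjusted p was 0.0173, 0.0269 and 0.0488. With an estimated correlation and no block it was 0.525, 0.746 and 0.853. The list of genes with a described promoter G-quadruplex was not called under PhenDC3 (adjusted p = 0.967), PhenDC6 (adjusted p = 0.967) or PDS (adjusted p = 0.856). Its members went both ways: MYC rose by 0.57 ± 0.07 under PhenDC3, and VEGFA rose by 0.94 ± 0.08 and BCL2 fell by 0.37 ± 0.06 under PDS. Other lists not called under PDS were immediate-early genes (adjusted p = 0.418), NF-kappaB and cytokines (adjusted p = 0.577), telomere maintenance (adjusted p = 0.846), YAP, TGF-beta and contractile genes (adjusted p = 0.967), metallothioneins (adjusted p = 0.981), markers of other cell types (adjusted p = 0.952), aryl hydrocarbon receptor targets (adjusted p = 0.625), NRF2 targets (adjusted p = 0.254) and ribosome biogenesis (adjusted p = 0.13). Only 3 of the cell-type markers were tested, and their median of 0.20 under PDS had the opposite sign to the list test. Under PhenDC3 the median and the list test also differed in sign for these markers, immediate-early genes, NF-kappaB genes and splicing factors, and under PhenDC6 for hypoxia and glycolysis genes; none of these was called.

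**Figure D1:**
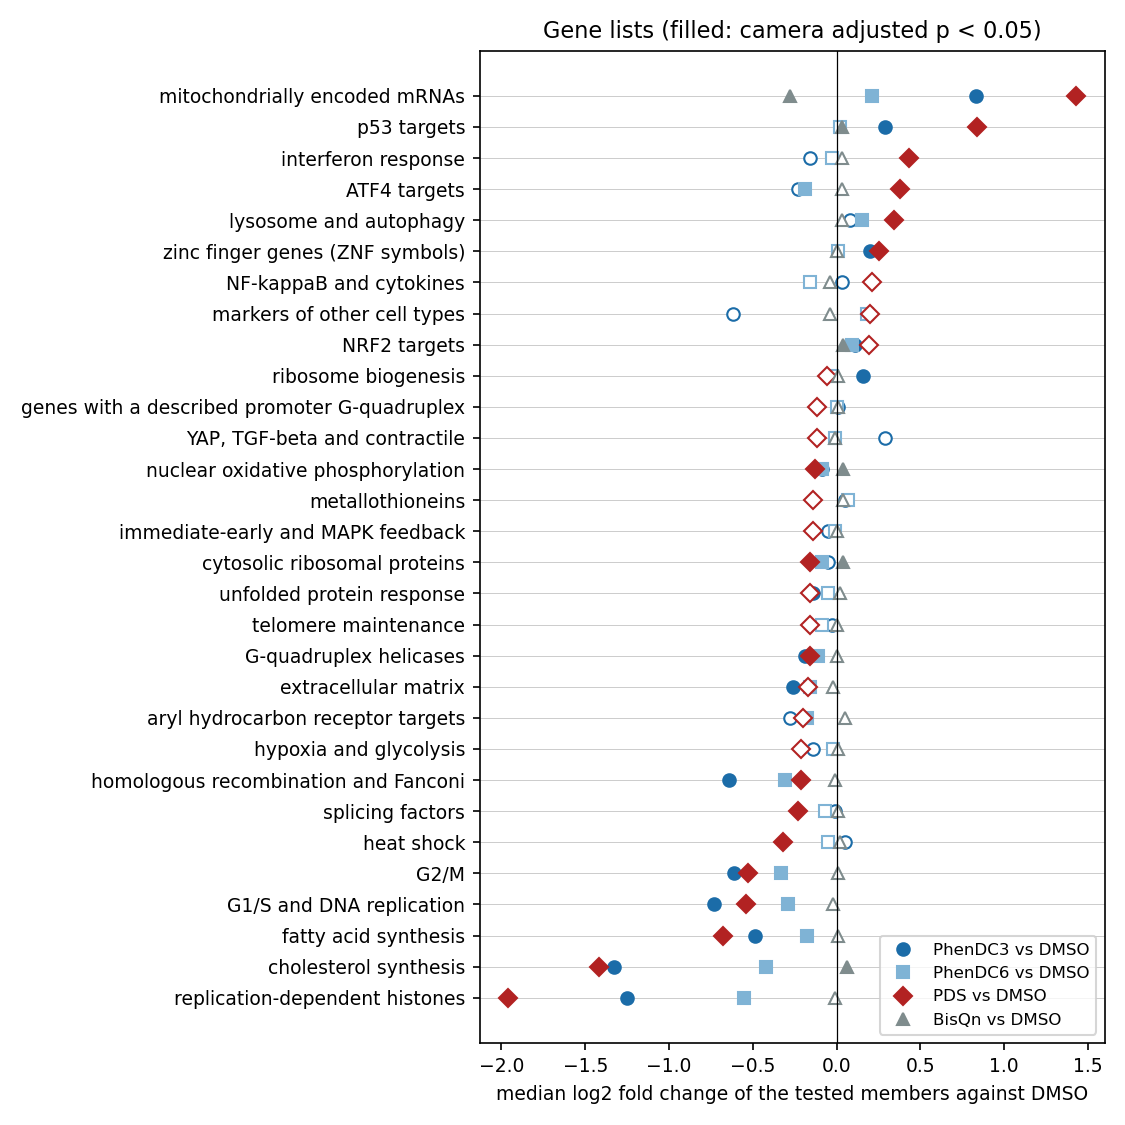
Median log2 fold change of each gene list's tested members (x axis) for each compound against DMSO, with 3 libraries per group; filled symbols passed camera at an adjusted p of 0.05. Histones reach -1.96 and mitochondrial mRNAs 1.43 under PDS.

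The mitochondrial RNAs changed unevenly along the mitochondrial genome. Their mRNAs took 0.999% ± 0.030 (SD, n = 3) of reads in DMSO, 2.17% ± 0.22 under PhenDC3, 1.36% ± 0.057 under PhenDC6, 3.43% ± 0.25 under PDS and 0.848% ± 0.048 under BisQn. The mitochondrial rRNAs took 10.1% ± 0.63 in DMSO, 9.22% ± 0.45 under PhenDC3, 7.35% ± 0.26 under PhenDC6, 8.04% ± 0.29 under PDS and 7.51% ± 0.49 under BisQn. MT-ND5 rose by 2.35 ± 0.12, 1.31 ± 0.12 and 2.77 ± 0.12 under PhenDC3, PhenDC6 and PDS. MT-RNR2 fell by 0.46 ± 0.06 under PDS, 0.59 ± 0.06 under PhenDC6 and 0.52 ± 0.06 under the control BisQn. Under PhenDC3 it stood at -0.07 ± 0.06 (adjusted p = 0.349). The other rRNA, MT-RNR1, fell by 0.49 ± 0.06 under PhenDC3, 0.46 ± 0.06 under PhenDC6 and 0.26 ± 0.06 under PDS. Under BisQn it stood at -0.30 ± 0.06 (adjusted p = 0.191). Both rRNAs were chosen after their values were seen.

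**Figure D2:**
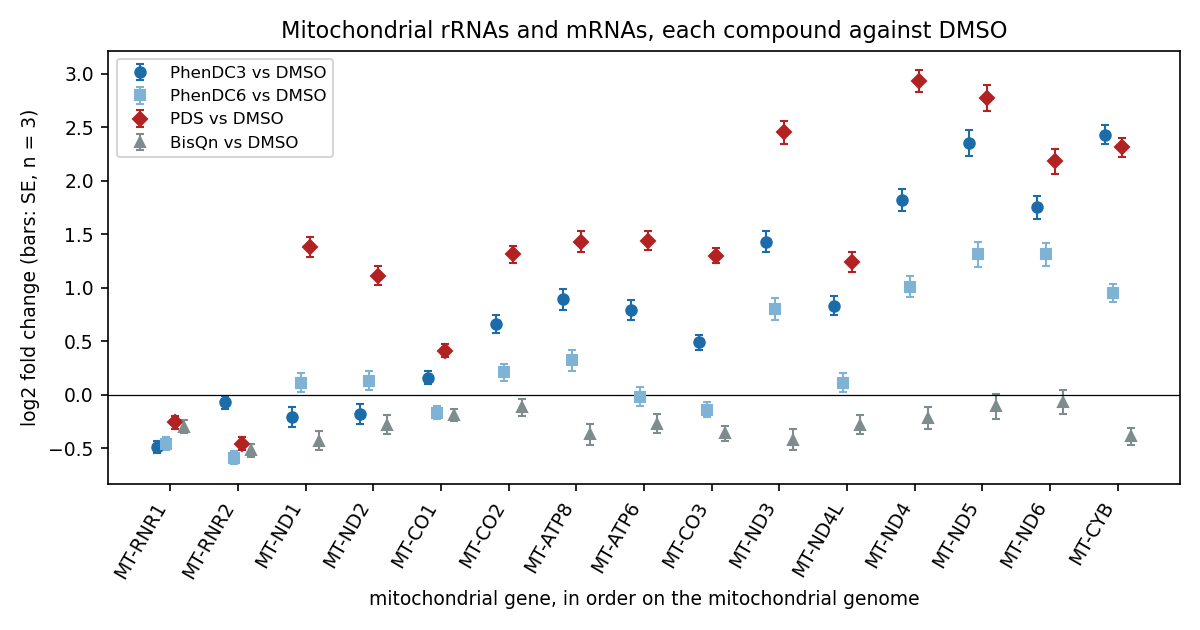
Log2 fold change against DMSO (y axis, points with SE, n = 3) of the mitochondrial rRNAs and mRNAs in their order on the mitochondrial genome (x axis). Under PDS, MT-RNR2 lies at -0.46 and MT-ND4 at 2.93.

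For BisQn, the control compound, few genes were called against DMSO. The 3 called genes all fell: MT-RNR2 (-0.52 ± 0.06), the tRNA MT-TP (-0.62 ± 0.09) and MTRNR2L12 (-0.47), a nuclear copy that can share reads with MT-RNR2. These 3 were chosen after their values were seen. Among 12970 genes above a log2 CPM of 1, 95% of log2 fold changes lay between -0.15 and 0.13. At an unadjusted p under 0.05 in the edgeR test there were 763 of 24752 genes, below the share of 0.05 that unchanged genes alone would give. The main test, which leaves out the pairing, may thus be too strict here. Its few calls therefore do not show that BisQn had no effect. DESeq2 called 12. Without the low-count filter the test called 84 genes, of which 38 rose and 46 fell. With the replicate block 18 genes were called, among them, also chosen after their values were seen, MT-CO3 (-0.36 ± 0.06), MT-ND1 (-0.43 ± 0.06), GRAMD1B (-0.34 ± 0.05), DMBT1 (-0.48 ± 0.07) and SPRY2 (0.20 ± 0.04). As a list, mitochondrial mRNAs fell (median -0.28, adjusted p = 2.95e-30, and adjusted p = 0.0486 with an estimated correlation), with 0 of 13 members called over all genes and 10 adjusted over the list alone. Targets of p53 (median 0.03, adjusted p = 0.000452, and adjusted p = 0.252 with an estimated correlation) and of NRF2 (median 0.04, adjusted p = 0.00133, and adjusted p = 0.437 with an estimated correlation) were called upward, with 0 members called, also when adjusted over the list alone. The NRF2 call was lost without DMSO replicate 3 (adjusted p = 0.305). Cholesterol synthesis (adjusted p = 0.0228, and adjusted p = 0.844 with an estimated correlation), ribosomal proteins (adjusted p = 0.000504, and adjusted p = 0.844 with an estimated correlation) and nuclear oxidative phosphorylation (adjusted p = 0.00135, and adjusted p = 0.756 with an estimated correlation) were also called upward. Without DMSO replicate 3 their adjusted p was 0.882, 0.661 and 0.526, and without BisQn replicate 2 it was 0.211, 0.954 and 0.532. Without BisQn replicate 1 it was 0.353 for cholesterol synthesis. ATF4 targets (adjusted p = 0.111) and the unfolded protein response (adjusted p = 0.117) were not called, but had an adjusted p of 0.0129 and 0.0357 with the replicate block, and of 0.855 and 0.799 with an estimated correlation and no block. The DDX42 change was -0.02 with a 95% interval from -0.13 to 0.1. Without DMSO replicate 1 or BisQn replicate 2 the count was 1, and without BisQn replicate 3 the count was 8.

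Untreated cells differed from DMSO cells in 1213 genes, 771 higher and 442 lower. With the stricter low-count filter 637 were higher and 605 lower. The sources used here do not state how untreated cells were handled, so the groups may differ in more than the vehicle. HAS2, a hyaluronan synthase, stood at 14.7 CPM untreated and 4.34 in DMSO (1.76 ± 0.09). TNFSF15 (1.3 ± 0.18), MYH16 (1.20 ± 0.06), ADGRG1 (1.19 ± 0.09) and FST (1.18 ± 0.11) were higher, and TBX10 (-0.90 ± 0.15), EID3 (-0.85 ± 0.12), RNF150 (-0.72 ± 0.18), EPB41L5 (-0.70 ± 0.12) and NELL2 (-0.68 ± 0.10) lower. Extracellular matrix genes were higher in 7 of 29 (10 adjusted over the list alone; adjusted p = 2.11e-07, and adjusted p = 0.0396 with an estimated correlation), with TNC at 0.85 ± 0.09 and LOX at 0.54 ± 0.07. Targets of p53 were higher in 6 of 27 (9 adjusted over the list alone; adjusted p = 3.22e-06, and adjusted p = 0.143 with an estimated correlation). NRF2 targets were lower in 6 of 22 and higher in 1 (9 and 4 adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.437 with an estimated correlation), with NQO1 at -0.41 ± 0.05. Homologous recombination genes (adjusted p = 0.00399, and adjusted p = 0.769 with an estimated correlation) and G1/S genes (adjusted p = 0.0167, and adjusted p = 0.855 with an estimated correlation) were called lower, with 0 of 24 and 1 of 27 members lower (0 and 1 adjusted over the list alone). Ribosomal proteins (adjusted p = 0.000138, and adjusted p = 0.824 with an estimated correlation) and nuclear oxidative phosphorylation (adjusted p = 0.00326, and adjusted p = 0.771 with an estimated correlation) were called higher, with 1 of 82 and 1 of 31 members higher (0 and 1 adjusted over the list alone). Without DMSO replicate 2 the adjusted p was 0.0687 and 0.476 for the first 2 of these lists, and without untreated replicate 1 it was 0.0623 and 0.243. For G1/S genes it was 0.0584 without untreated replicate 3. Without DMSO replicate 3 it was 0.173 and 0.131 for the last 2, and without untreated replicate 2 it was 0.128 and 0.208. The NRF2 call was lost without untreated replicate 3 (adjusted p = 0.0991), and that of RNF150 without untreated replicate 2 (0.0931) or 3 (0.0684) or DMSO replicate 1 (0.0993) or 2 (0.0815). ATF4 targets, cholesterol synthesis, immediate-early genes and metallothioneins were not called (adjusted p = 0.0682, 0.14, 0.136 and 0.535), but were with the replicate block (adjusted p = 0.00664, 0.00581, 0.021 and 0.0405). With an estimated correlation and no block the adjusted p was 0.835, 0.905, 0.769 and 0.911. With the replicate block the count was 2657, and without untreated replicate 2 it was 737.

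Against BisQn in place of DMSO, PhenDC3 changed 11365 genes (5600 up), PhenDC6 6443 (2841 up) and PDS 11561 (5699 up). SWINGN rose by 3.70 ± 0.15, 2.04 ± 0.16 and 3.61 ± 0.15 in that order. Under PhenDC3, NUDT19-DT (2.97 ± 0.13) and GCNA (2.72 ± 0.11) rose and KRT15 (-2.09 ± 0.14) fell. Under PhenDC6, CEMIP (1.95 ± 0.18) and DDX42 (1.61 ± 0.06) rose and NEK3 (-1.22 ± 0.13) fell, and under PDS, PINCR (3.65 ± 0.15) and GRIN2C (2.89 ± 0.16) rose and INSIG1 (-2.04 ± 0.14) fell. With the stricter low-count filter the counts for PhenDC3 and PDS were 7545 and 7556. Lists called against BisQn with the replicate block but not without it were ribosomal proteins under PhenDC3 (adjusted p = 0.0204, against 0.053), the unfolded protein response under PhenDC6 (0.0254, against 0.0763) and PDS (0.0197, against 0.113), and extracellular matrix (0.0217, against 0.111) and helicases (0.0398, against 0.0549) under PDS. In that order, the adjusted p with an estimated correlation and no block was 0.917, 0.782, 0.799, 0.537 and 0.718.

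The ligands shared part of their response. SWINGN, CCT6P3, DDX42, PGBD5, CEMIP, ZNF316, MIR3189, GPR75 and GDF15 rose under all 3 ligands and INSC fell, with DDX42 at 1.93 ± 0.06, 1.59 ± 0.06 and 2.08 ± 0.06 under PhenDC3, PhenDC6 and PDS. The MIR3189 call under PhenDC6 was lost without DMSO replicate 1 (adjusted p = 0.063) or PhenDC6 replicate 3 (0.0545). In all, 1848 genes rose and 2219 fell under all 3, a total of 4067. Independent lists of these sizes would share 118 and 168. Simulated unchanged groups shared 0, which the test would give almost regardless of the shared control, so that 0 adds no support. Across genes, which are not independent replicates, the log2 fold changes of PhenDC3 and PhenDC6 correlated with Pearson r = 0.74 and Spearman rho = 0.72, those of PhenDC3 and PDS with 0.66 and 0.65, and those of PhenDC6 and PDS with 0.61 and 0.61. Unchanged groups sharing a control gave r = 0.52 and rho = 0.46. The covariances were 0.155, 0.224 and 0.132, against simulated values of 0.0288, 0.029 and 0.0288. BisQn correlated with PhenDC3, PhenDC6 and PDS by r = 0.13, 0.28 and 0.15, where the simulated r was 0.51. The covariances were 0.0201, 0.0269 and 0.0227, beside simulated values of 0.029, 0.0289 and 0.0289. The simulated r holds for groups that are both unchanged. Real changes under a ligand widen the spread of its fold changes, so a real r cannot be set directly against a simulated one. For BisQn, this alone can bring r below 0.51. The r of BisQn with the ligands were also not stable. Without DMSO replicate 3 they were 0.27, 0.446 and 0.274. With BisQn taken against untreated cells they were -0.00308, 0.0335 and -0.00404, and with the stricter filter -0.0816, -0.048 and -0.0936. The simulation left out the pairing of the replicate numbers, by which libraries of a number deviate together and partly cancel in a fold change. The simulated r and covariances may therefore be too high. Part of the excess in overlap may come from the shared DMSO libraries.

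PhenDC3 and PhenDC6, bisquinolinium phenanthroline dicarboxamides that differ in where the quinolinium is attached, differed in 6361 genes, with the larger change under PhenDC3 in 5876. Among 4947 genes called in the same direction under both, the median absolute change was 0.52 for PhenDC3 and 0.30 for PhenDC6. HMGCS1 (-1.54 ± 0.20), HSD17B7 (-1.41 ± 0.10), MVD (-1.29 ± 0.18) and ACAT2 (-1.22 ± 0.19) were lower under PhenDC3, and NUDT19-DT (2.40 ± 0.12), HCN2 (1.81 ± 0.18), SWINGN (1.66 ± 0.12), MRNIP (1.58 ± 0.12) and CPM (1.57 ± 0.19) higher. Cholesterol synthesis was lower in 23 of 24 (24 adjusted over the list alone; adjusted p = 8.09e-35, and adjusted p = 0.0963 with an estimated correlation). Targets of p53 were higher in 19 of 27 and lower in 1 (21 and 1 adjusted over the list alone; adjusted p = 7.81e-15, and adjusted p = 0.0263 with an estimated correlation). Immediate-early genes were called only with the replicate block (adjusted p = 0.0487, against 0.132, and 0.767 with an estimated correlation and no block). CEMIP (-0.13, 95% interval -0.47 to 0.2), PGBD5 (0.19, 0.04 to 0.33) and INSC (-0.42, -0.83 to -0.02) had no called difference (adjusted p = 0.601, 0.0535 and 0.121).

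PhenDC3 and PDS, a pyridine dicarboxamide, differed in 8381 genes, and neither compound had the larger change throughout (4198 larger under PhenDC3 and 4183 under PDS). TBX10 (3.29 ± 0.18), NUDT19-DT (2.96 ± 0.13) and GCNA (1.83 ± 0.10) were higher under PhenDC3, and PINCR (-2.87 ± 0.14), FUCA1 (-1.96 ± 0.13), NUPR1 (-1.92 ± 0.14), ASXL3 (-1.90 ± 0.16) and CSTA (-1.85 ± 0.17) lower. Targets of p53 were lower under PhenDC3 in 22 of 27 (22 adjusted over the list alone; adjusted p = 2.4e-39, and adjusted p = 0.000564 with an estimated correlation). Interferon genes were lower in 22 of 30 with 1 higher (22 and 2 adjusted over the list alone; adjusted p = 6.65e-11, and adjusted p = 0.0263 with an estimated correlation). SWINGN (0.09, 95% interval -0.14 to 0.32), CCT6P3 (0.14, -0.05 to 0.33) and INSC (-0.32, -0.73 to 0.09) had no called difference.

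PhenDC6 and PDS differed in 7836 genes, with the larger change under PDS in 6698. HMGCS1 (2.05 ± 0.21), the pseudogene SMPD4P1 (1.78 ± 0.12), INSIG1 (1.69 ± 0.14) and LINP1 (1.60 ± 0.13) were higher under PhenDC6, and PINCR (-3.78 ± 0.15), NECTIN4 (-2.88 ± 0.18), CPM (-2.55 ± 0.18), ASXL3 (-2.32 ± 0.17) and ARRDC4 (-2.23 ± 0.21) lower. All 27 p53 targets were lower under PhenDC6 (27 adjusted over the list alone; adjusted p = 1.78e-88, and adjusted p = 3.05e-05 with an estimated correlation), as were all 13 mitochondrial mRNAs (13 adjusted over the list alone; adjusted p = 1.3e-46, and adjusted p = 0.0157 with an estimated correlation). Ribosomal proteins were called only with the replicate block (adjusted p = 0.0397, against 0.0736, and 0.92 with an estimated correlation and no block). INSC (0.1, 95% interval -0.29 to 0.49) and GPR75 (-0.21, -0.46 to 0.04) had no called difference.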

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

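The tests on mitochondrial RNAs were chosen after the result was seen. Ligands moved some genes in opposite directions: 26 genes for PhenDC3 and PhenDC6, 439 for PhenDC3 and PDS, and 145 for PhenDC6 and PDS. All of these also had a called direct difference. Opposite calls in the same fit make that almost certain, so it adds no support. RAB27B stood at -0.40 under PhenDC3 and 0.40 under PhenDC6, PTK2B at -0.62 under PhenDC3 and 0.63 under PDS, and CTH at -0.52 under PhenDC6 and 0.69 under PDS. ATF4 targets fell under PhenDC6 and rose under PDS (direct adjusted p = 1.08e-23; adjusted p = 0.0952 with an estimated correlation).

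Lists called in opposite directions under BisQn and a ligand were also compared directly. These lists, like the ATF4 targets, were chosen by their opposite calls. A low direct p at the preset correlation largely follows from that choice and adds little. For mitochondrial mRNAs the adjusted p was 5.68e-22 against PhenDC3, 1.43e-20 against PhenDC6 and 6.01e-49 against PDS (adjusted p = 0.0952, 0.0963 and 0.0146 with an estimated correlation). For cholesterol synthesis, with a median of 0.06 under BisQn, it was 7.96e-26, 2.2e-08 and 5.35e-29 (adjusted p = 0.138, 0.491 and 0.126 with an estimated correlation). For cytosolic ribosomal proteins, with a median of 0.04 under BisQn, it was 3.63e-06 against PhenDC6 and 5.78e-05 against PDS (adjusted p = 0.782 and 0.807 with an estimated correlation). For nuclear oxidative phosphorylation it was 5.38e-05 and 0.00372 (adjusted p = 0.633 and 0.771 with an estimated correlation). The BisQn calls of the last 3 lists were lost without single libraries, and that of mitochondrial mRNAs was not. Without DMSO replicate 3, BisQn replicate 1 or BisQn replicate 2 the adjusted p for cholesterol synthesis was 0.882, 0.353 and 0.211. Without DMSO replicate 3 or BisQn replicate 2 it was 0.661 and 0.954 for ribosomal proteins and 0.526 and 0.532 for oxidative phosphorylation.

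The list of mitochondrial mRNAs was called upward under PhenDC3, PhenDC6 and PDS (11, 6 and 13 of 13 rose, and 1 fell under PhenDC6), but neither rRNA rose; with an estimated correlation the adjusted p was 0.154, 0.291 and 0.0263. Reads counted on nuclear copies were at most 1.56% of those of the mitochondrial mRNAs in any library. Reads of such copies that were counted on the mitochondrial genes would not show in this share, so they stay open as a source. A rise of all mitochondrial RNAs alike is argued against by the lower rRNA, which lay at least 1.32 (log2) below the median mRNA under PhenDC3 and PDS. Across the 12 heavy-strand mRNAs the fold change tended to increase with order from the promoter, with Spearman rho = 0.92, 0.64 and 0.65 under PhenDC3, PhenDC6 and PDS. The permutation p was 9e-05, 0.029 and 0.026 (adjusted p = 0.00036, 0.039 and 0.039), and under BisQn rho was 0.14. The permutation treats neighbouring genes as independent, which they may not be, so these p may be too small. The neighbours MT-ND4L and MT-ND4 stood far apart, at 0.83 and 1.82 under PhenDC3, 0.11 and 1.01 under PhenDC6, and 1.24 and 2.93 under PDS. MT-ND6, on the light strand, stood at 1.75, 1.31 and 2.18, but without the counting strand its reads may come from heavy-strand RNA. Heavy-strand tRNAs, at under 7 CPM in DMSO, were not part of the test. The late MT-TG (3.64, 2.47 and 4.15), MT-TR (4.04, 2.92 and 4.83), MT-TH (4.19, 2.49 and 3.99), MT-TS2 (3.63, 1.67 and 3.01) and MT-TL2 (4.03, 1.39 and 2.41) rose. The early MT-TV (-1.68, -1.02 and -0.05), MT-TL1 (-0.95, -0.49 and 0.01) and MT-TM (-1.51, -0.70 and 0.07) did not. Other early ones went both ways: MT-TF stood at -1.91, -0.57 and 0.95, MT-TI at 1.61, -0.76 and 0.25, and MT-TW at 0.61, -0.60 and 1.25. Between the early and late ones, MT-TK rose (2.46, 1.15 and 4.03) and MT-TD stood at 1.28, -1.35 and 0.9. Both were low in DMSO, at 0.227 and 0.146 CPM. MT-TT, the last at 0.546 CPM, stood at 1.22, -1.85 and -1.28, against that order under PhenDC6 and PDS. For the mRNAs of the heavy strand, an effect of distance may contribute, which stays a hypothesis found on the same data.

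Genes with ZNF symbols were called upward under PhenDC3 and PDS, with 204 and 230 of 425 rising and 54 and 42 falling (adjusted p = 0.165 and 0.126 with an estimated correlation). After a trend on GC content and transcript length was removed from all genes, their medians were 0.21 and 0.20, against 0.20 and 0.25 before, so that trend does not account for the higher median. Reads shared between related zinc finger genes were not tested and stay open, as does an effect of the ligands.

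No split could reach a share under 0.05, since 6 libraries make 10 splits; the real split was the 1 with as many genes in each of the 11 comparisons. The highest count of another split was 31 for PhenDC6 against BisQn, where the real count was 6443, and 0 in the others. Those real counts were 11008, 5677, 11196 and 3 for PhenDC3, PhenDC6, PDS and BisQn against DMSO, 1213 for untreated cells, 11365 and 11561 for PhenDC3 and PDS against BisQn, and 6361, 8381 and 7836 between ligands. With the numbers taken as pairs, 3 other splits in each comparison parted all pairs, and these gave 0 genes, while the split with 31 kept a pair together. Every other split mixes libraries of both groups, so the difference between the groups enters the spread. Low counts there follow largely from the design and give no background for the real counts.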

How the results depend on the processing

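Leaving out libraries for the correlations was chosen after seeing the data; the other alternatives were planned. RLE scaling and limma-voom moved no count of changed genes by more than 1.5 times. For BisQn against DMSO (3 genes) the count was 84 without the low-count filter, 18 with the replicate block, 13 with only the groups compared and 12 with DESeq2. The block gave 2657 for untreated cells, and changed no other count beyond 1.5 times; it brought 53 named genes past the threshold and removed none, and brought 17 list calls and removed 1. The stricter low-count filter, which tests fewer genes, gave 7461 for PDS against DMSO, and 7545 and 7556 for PhenDC3 and PDS against BisQn. Falls outnumbered rises for the 3 ligands in the main test, but this balance turned with some settings. Against DMSO, rises and falls were 5619 and 5270 under PhenDC3 and 5616 and 5452 under PDS with RLE scaling. They turned as well without the low-count filter, with only the groups compared and with DESeq2. Against BisQn they turned under these same settings, but in the main test falls still outnumbered rises (5600 and 5765 under PhenDC3, 5699 and 5862 under PDS). With the stricter filter, rises and falls against DMSO were 2446 and 2316 under PhenDC6 and 3799 and 3662 under PDS. That filter also turned the balance of PhenDC3 against PhenDC6 (2455 and 2639) and PDS (2872 and 3014), the latter also with only the groups compared.

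An adjusted p under 0.01 gave 3476 for PhenDC6 against DMSO, 601 for untreated cells, 4037 for PhenDC6 against BisQn, 4076 for PhenDC3 against PhenDC6 and 2654 for genes shared by the 3 ligands. An absolute log2 fold change of at least 1 gave 1685, 323, 1775 and 0 for PhenDC3, PhenDC6, PDS and BisQn against DMSO, 76 for untreated cells, 1774, 418 and 1893 for the ligands against BisQn, 449, 963 and 914 between ligands, and 178 for shared genes. These are stricter by construction.

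Leaving out each library gave 9794 to 10275 (PhenDC3), 3995 to 5438 (PhenDC6), 9854 to 10456 (PDS), 1 to 8 (BisQn) and 737 to 916 (untreated) against DMSO, 10022 to 10628, 4463 to 5783 and 10195 to 10746 for the ligands against BisQn, 4691 to 5664 for PhenDC3 against PhenDC6, 6944 to 7583 for PhenDC3 against PDS, 6184 to 6974 for PhenDC6 against PDS and 3006 to 4087 for shared genes.

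Taking the second compound against untreated cells removes the shared control. Then r was 0.555 for PhenDC3 and PhenDC6, 0.569 for PhenDC3 and PDS, and 0.476 for PhenDC6 and PDS. For BisQn with PhenDC3, PhenDC6 and PDS it was -0.00308, 0.0335 and -0.00404. The covariances of the ligand pairs, in the same order, were 0.135, 0.203 and 0.109, against 0.155, 0.224 and 0.132 with DMSO. Most of the covariance thus stayed, so the lower r does not show that the shared control made most of the likeness. With the stricter filter r was 0.878, 0.78 and 0.765 for PhenDC3 and PhenDC6, PhenDC3 and PDS, and PhenDC6 and PDS, and -0.0816, -0.048 and -0.0936 for BisQn with PhenDC3, PhenDC6 and PDS. Leaving out each library gave 0.663 to 0.754, 0.634 to 0.687 and 0.543 to 0.645 for the ligand pairs, and 0.12 to 0.27, 0.227 to 0.446 and 0.117 to 0.274 for BisQn with PhenDC3, PhenDC6 and PDS.

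Lists whose direction turned while called with or without the library were all of BisQn against DMSO. Given are the adjusted p there and the range over all libraries left out: immediate-early genes without DMSO replicate 1 (0.0448; to 0.854), cholesterol synthesis without DMSO replicate 3 (0.882; from 0.000146), ribosomal proteins without DMSO replicate 3 (0.661; 1.76e-09 to 0.954), histones without BisQn replicate 1 (0.0246; 0.0205 to 0.585), ribosome biogenesis without BisQn replicate 2 (0.00948; 0.0034 to 0.522) and splicing factors without BisQn replicate 2 (0.011; 0.00338 to 0.999). Uncalled, ribosome biogenesis and splicing factors also turned without DMSO replicate 1 or 3, immediate-early genes without BisQn replicate 2 or 3, and histones without DMSO replicate 2 or 3. Except where stated, the cause was not tested. With an estimated correlation 136 list calls were lost. The rotation test fry, which does not set a list against other genes, removed 13 calls and brought 37. Removed for BisQn were cholesterol synthesis, ribosomal proteins, NRF2 targets, oxidative phosphorylation and p53 targets (adjusted p = 0.764, 0.699, 0.281, 0.467 and 0.11). For untreated cells these were ribosomal proteins, G1/S, homologous recombination, NRF2 targets and oxidative phosphorylation (adjusted p = 0.344, 0.548, 0.247, 0.0529 and 0.165), and for PhenDC6 ribosomal proteins (adjusted p = 0.169), all against DMSO. At this depth the simulated test called 31 of 50 genes changed 1.3-fold.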

Other observations

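The matching on GC content of the 5' UTR itself was chosen after the result was seen. The 5' UTRs come from an annotation of a later genome build than the counts. Genes of telomere maintenance were not called as a list under PhenDC3, PhenDC6 or PDS (adjusted p = 0.967, 0.684 and 0.846), with 3, 2 and 4 of 14 rising and 5, 1 and 6 falling. Among them, TERF2 rose by 1.08 ± 0.07, 0.36 ± 0.07 and 1.12 ± 0.07 under PhenDC3, PhenDC6 and PDS, and STN1 fell by 0.87 ± 0.06, 0.36 ± 0.06 and 0.58 ± 0.06 (edgeR, n = 3). The cytokine LIF rose by 0.88 ± 0.08, 0.39 ± 0.08 and 1.16 ± 0.08, and BIRC3 fell by 1.37 ± 0.17, 0.66 ± 0.16 and 0.89 ± 0.16.

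Genes with a G-quadruplex motif in the 5' UTR had a slightly higher response to the ligands than genes without. Among 12152 protein-coding genes matched on GC decile and 5' UTR length, 1557 had a motif. The difference of medians was 0.061 ± 0.012 under PhenDC3, 0.032 ± 0.008 under PhenDC6 and 0.064 ± 0.014 under PDS, and -0.002 under BisQn. The SE came from a bootstrap of genes, and the permutation p was 1e-04 for each ligand, the smallest 10000 permutations can give. Genes are not independent replicates and were all measured on the same plates. Neither the SE nor the p therefore measures the spread between plates. A difference above 0.05 under every ligand had been set in advance as what a motif effect needs, and PhenDC6 at 0.032 missed it. It missed by more than its SE, but that SE leaves out the plates, so a common motif effect of that size stays undecided. Matching left 0.61 ± 0.08, 0.57 ± 0.10 and 0.67 ± 0.10 of the difference under PhenDC3, PhenDC6 and PDS, above the preset limit of 0.5. These SE are large beside the distance from that limit, and genes of 1 decile can still differ in GC content. An account by GC content alone therefore stays open for all 3 ligands. Matching on the GC content of the 5' UTR left 0.066, 0.035 and 0.075. Since PhenDC6 had smaller changes in general, a fixed size asks more of it. Motifs in promoters were not analysed here, and a smaller motif effect may remain.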
